A study of Mus musculus with 14 samples.

How the data were processed

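The peak lists of 2 ChIP-seq libraries made with an antibody against AHCY (replicates 1 and 2) were analysed, out of 14 libraries in the series. The cells were E14 mouse embryonic stem cells in serum-free medium, per the labels. The IgG ChIP-seq library and the 11 RNA-seq libraries (control hairpin, hairpins against Ahcy, EdU fractions) are not analysed here. The submitters' processing notes name the mouse build mm9 and the tools Bowtie and TopHat, without roles or versions.

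Each list gives the chromosome, start, end, name and score of every peak, 1 list per library, per the file headers and columns. The score is the deposited per-peak value of the authors' peak caller. The caller, its version, its limit and other filters are not given in the sources used here. The lowest score in both lists is 50, and what the score measures is not stated. Its floor resembles that of callers whose score is a scaled logarithm of a p-value, which would depend on read depth as well as on enrichment, so scores are not read as enrichment. Scores were used to rank peaks within their own list, and a ratio of scores between lists was used only to compare chromosomes with each other. The header of the replicate 1 list speaks of a pool without saying what was pooled and names no control, per the file headers. The header of the replicate 2 list names an IgG pool, which was taken to be its control. Whether the lists used the same control is therefore unknown, and so is the read depth of each library.

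Starts were converted from counting from 0 to counting from 1. The build was checked against the gene table at hand, which is of the later GRCm38 assembly: 19 peaks of replicate 1 and 31 of replicate 2 on chromosome 7 lie beyond its last gene there, so the lists are not on that assembly. No coordinates were converted and no genes were assigned to peaks. A test of peaks near transcription start sites and a test of 13 gene lists, both written before the data were examined, were therefore not run.

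The comparisons, the alternatives to each choice and the rule for naming regions were fixed before the data were examined, apart from those named as chosen later or unplanned. A peak was shared when at least 1 bp lay in a peak of the other list. The number shared was compared with 1000 random placements of the replicate 1 peaks, widths kept, within the span from the first to the last peak of either list on their own chromosome (one-sided). Median scores of shared and unshared peaks were compared within each list by a two-sided permutation test with 100000 resamples. Scores of shared pairs, each peak with its best-scoring partner, were related by Spearman's rho and Pearson's r of log scores with 100000 permutations, and again without the 2 peaks farthest from the median. Overlapping peaks were merged into shared regions. Their number per chromosome was tested against that expected from its span by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 20 chromosomes. Because peaks cluster, these p-values are too small, and counts and ratios lead. The regions named are the 10 with the best mean of their 2 within-list score ranks, the 5 widest, and the best-ranked 2 on each chromosome past the density test.

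Chosen after the data were seen were the comparisons with and without chromosomes 6 and 8 (for the density of peaks also with each replicate alone, and without the stretches of chromosomes 11 and 14 where replicate 2 had a local surplus), the ratio of peak numbers per chromosome, windows of 5 Mb and 1 Mb, placement by moving peaks 20 to 500 kb, and the list of best regions outside chromosomes 6 and 8. Also unplanned were the division into 4 score groups, the distance between midpoints, the best 100 peaks and the best peaks without a partner. Each 5 Mb window of an autosome was tested for a surplus of replicate 2 peaks by a one-sided exact binomial test against the pooled proportion on the 15 autosomes other than 6, 8, 11 and 14. Shares and ratios carry exact 95% intervals (Clopper-Pearson), which cover counting error only. The alternatives were other overlap rules (50% of the shorter peak, a reciprocal 50%, within 500 bp), the better-scoring 50% of each list, lists of equal length, autosomes only, placement over all chromosomes, peak width in place of score, and each replicate alone. The overlap step was tested on simulated data, where it recovered 1000 of 1000 planted shared peaks with 0 false ones among 4710 peaks, planted ones included. Planted peaks were shifted copies that still overlapped simulated replicate 2 peaks, and all others lay at least 20 kb from any. Correct code could give no other outcome, so this checks the code only and not how often unrelated peaks overlap. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.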

Results

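AHCY is S-adenosylhomocysteine hydrolase, the enzyme that breaks down S-adenosylhomocysteine, the by-product and inhibitor of methyl transfer reactions. The series holds 14 libraries from mouse embryonic stem cells of the E14 line, a widely used male line, which were grown without serum in the presence of LIF and inhibitors of MEK and GSK3. For chromatin immunoprecipitation with sequencing (ChIP-seq) there are 3 libraries, of which 2 were made with an antibody against AHCY and 1 with control IgG. The other 11 are RNA-seq libraries: 2 from cells with a control short hairpin RNA, 5 from cells with a hairpin against Ahcy and 4 from fractions separated by EdU, a label of newly made DNA. The values reported here come from the peak lists of the 2 AHCY ChIP-seq libraries, replicates 1 and 2. The IgG and RNA libraries are not analysed here. A peak list gives no read number, so the sequencing depth behind each peak is unknown.

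The AHCY ChIP-seq libraries address where in the genome AHCY lies on chromatin. Replicate 1 had 4465 peaks and replicate 2 had 11733. Most of the surplus lay on chromosomes 6 and 8, which held 475 peaks (10.6% of the list) in replicate 1 and 6291 (53.6%) in replicate 2. On all other chromosomes together the numbers were closer, at 3990 and 5442. The peaks were of similar width, with a median of 1576 bp (interquartile range 1186 to 2126 bp) in replicate 1 and 1511 bp (1119 to 2092 bp) in replicate 2. They covered 7.92 Mb and 20.5 Mb of the genome. The median peak score was 67.1 in replicate 1 and 73.0 in replicate 2, and the highest scores were 346.9 and 1307.

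**Figure D1:**
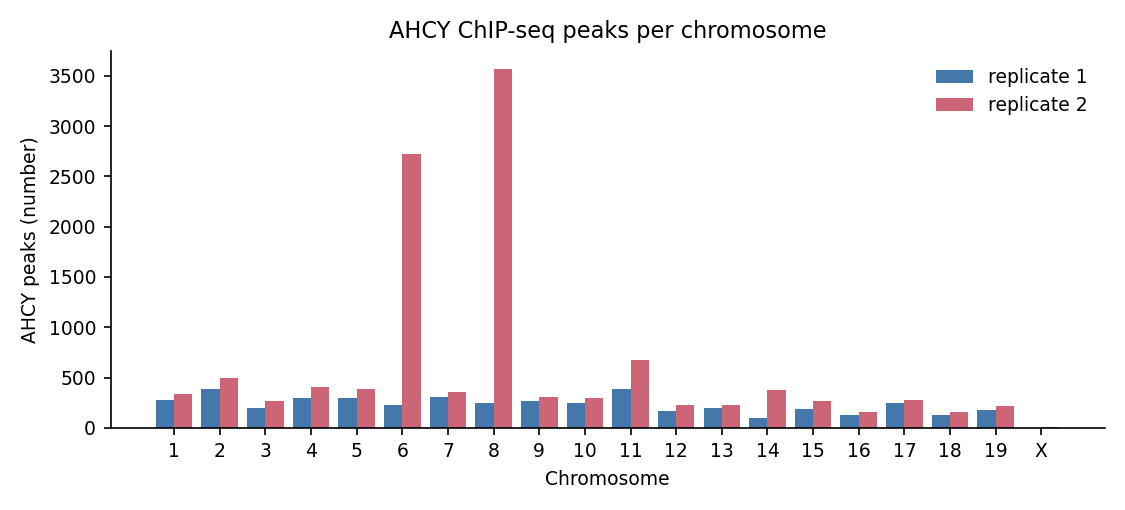
Number of AHCY ChIP-seq peaks on each chromosome in replicate 1 (blue) and replicate 2 (red). The bars of chromosomes 6 and 8 rise from 228 and 247 peaks in replicate 1 to 2720 and 3571 in replicate 2.

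Chromosome by chromosome, replicate 2 had 11.9 times as many peaks as replicate 1 on chromosome 6 (exact 95% interval 10.4 to 13.7) and 14.5 times as many on chromosome 8 (12.7 to 16.5). Chromosome 14 followed with 96 and 378 peaks, a ratio of 3.94 (3.14 to 4.98), and chromosome 11 with 390 and 674, a ratio of 1.73 (1.52 to 1.96). On the remaining 15 autosomes the ratio lay between 1.13 and 1.46, and it was 1.25 over these chromosomes pooled. In replicate 1 itself, chromosomes 6 and 8 were ordinary: by peaks per Mb they ranked 13 and 10 among 20 chromosomes. Chromosome X had 0 peaks in replicate 1 and 6 in replicate 2. Of these 6, 3 were neighbours between positions 166414605 and 166426070 of the mm9 build, with scores of 313.8, 204.6 and 1307, the last being the highest score of the replicate 2 list. These intervals, like the others given for shares, cover counting error only, and neighbouring peaks are not independent of each other.

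The surplus ran along the whole of chromosomes 6 and 8 but was mostly local on chromosomes 11 and 14. In windows of 5 Mb, 56 of the 57 windows of chromosomes 6 and 8 (98.2%) had a replicate 2 to replicate 1 ratio, with 1 added to both counts, above 2.67, the 95th percentile of the windows on the other 17 autosomes. The median of this ratio was 10.75 on chromosomes 6 and 8 and 1.24 on the others. Of the 444 windows on the other autosomes, 5 passed an adjusted threshold of 0.05 for a surplus of replicate 2 peaks (one-sided exact binomial test, Benjamini-Hochberg adjustment), compared with 49 of the 57. One was the window from 95 to 100 Mb of chromosome 11, with 42 peaks in replicate 1 and 211 in replicate 2. The other 4 were the neighbouring windows from 45 to 65 Mb of chromosome 14, with 2 and 38, 0 and 23, 0 and 114, and 6 and 57 peaks. In windows of 1 Mb, the stretch on chromosome 11 narrowed to 96 to 98 Mb, with 22 and 176 peaks, against 368 and 498 on the rest of the chromosome. From 47 to 63 Mb of chromosome 14, replicate 1 had 0 peaks and replicate 2 had 211, against 96 and 167 on the rest of that chromosome. Outside the stretches the ratio was 1.35 on chromosome 11 and 1.74 on chromosome 14. The latter lay above the 1.13 to 1.46 of the 15 autosomes other than 6, 8, 11 and 14. Shared pairs of chromosome 14, all outside its stretch, had a mean log2 ratio of replicate 2 to replicate 1 scores of 0.621. This was the highest among the other 17 autosomes, so a smaller surplus may extend beyond the stretch. The windows and both stretches were chosen after the peak positions had been seen.

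**Figure D2:**
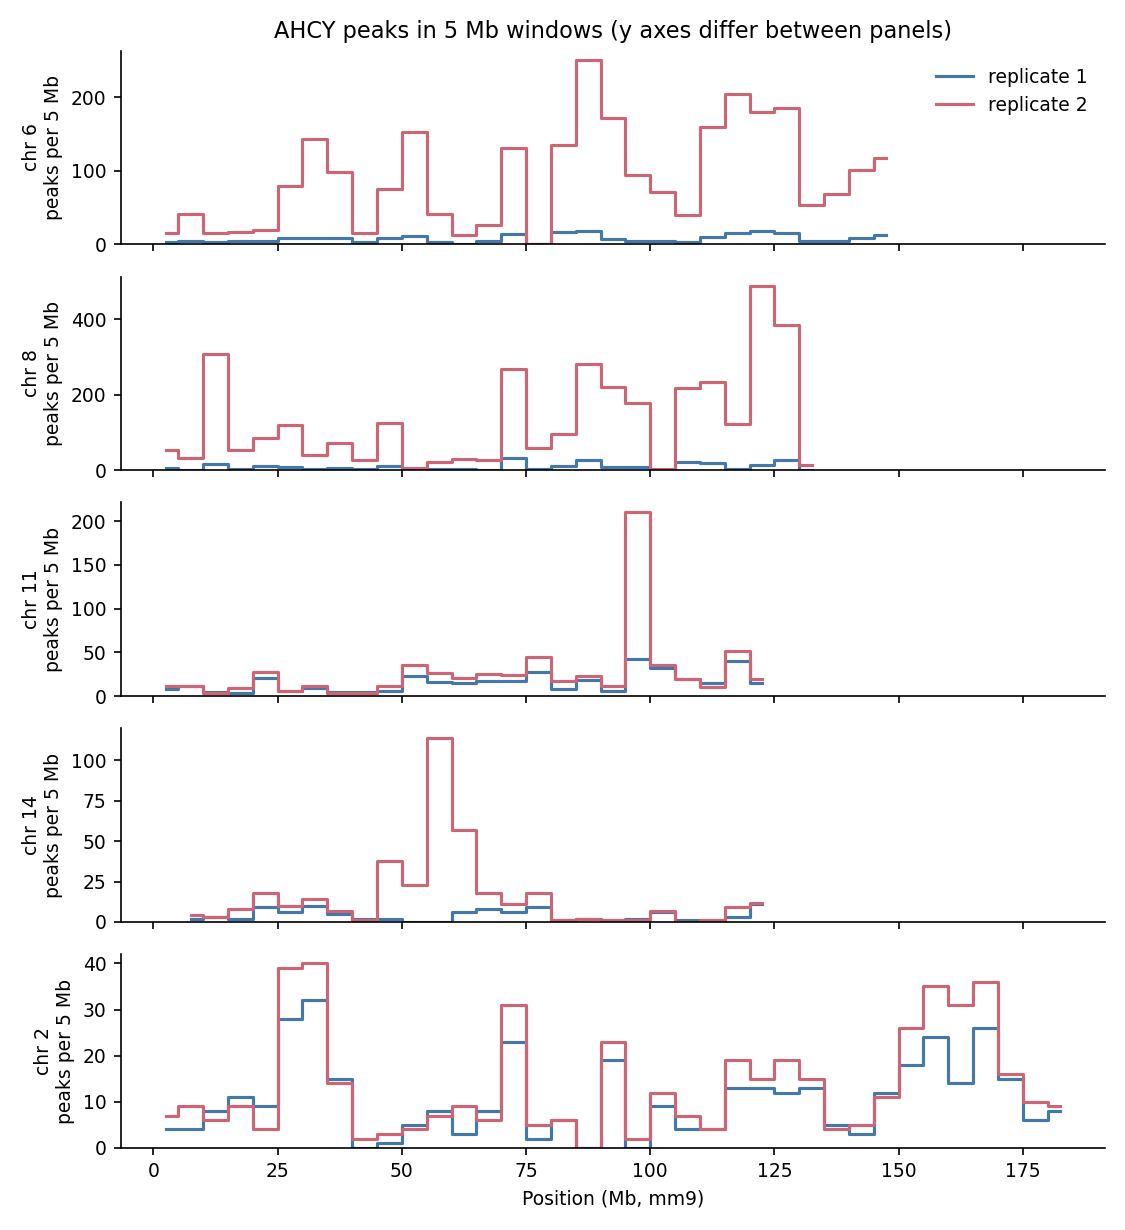
Number of AHCY peaks in 5 Mb windows along chromosomes 6, 8, 11, 14 and 2 (mm9 position in Mb) in replicate 1 (blue) and replicate 2 (red), with a separate vertical scale for each chromosome. Replicate 2 lies above replicate 1 in 56 of 57 windows of chromosomes 6 and 8 by more than the 95th percentile of the other autosomes, and on chromosomes 11 and 14 the surplus is mostly local.

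How far the replicates found the same sites was measured by overlap of at least 1 bp. Of the replicate 1 peaks, 2296 of 4465 (51.4%, exact 95% interval 49.9 to 52.9%) overlapped a replicate 2 peak. Of the replicate 2 peaks, 2312 of 11733 did so (19.7%, 18.99 to 20.44%). On chromosomes 6 and 8, 407 of 475 replicate 1 peaks were shared (85.7%, 82.2 to 88.7%), while 413 of 6291 replicate 2 peaks there were (6.56%). On the other chromosomes 1889 of the replicate 1 peaks (47.3%) and 1899 of the replicate 2 peaks (34.9%) were shared. The share of replicate 1 peaks with a partner was higher on chromosomes 6 and 8 than elsewhere, with an odds ratio of 6.66 (two-sided Fisher's exact test over peaks, p = 1.21e-61). Replicate 2 peaks are also denser there, so that random placement alone gave a share of 7.95% on chromosomes 6 and 8 and 0.945% elsewhere. Moving the peaks by 20 to 500 kb gave 18.6% and 2.10%. Chromosomes 6 and 8 were chosen for their many replicate 2 peaks, which by themselves raise the share with a partner. Fisher's exact test was therefore bound to lean this way and adds no separate evidence. Peaks of 1 pair of libraries are not independent replicates, so its p-value is also too small.

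The number of shared peaks was far above that of random placement. When the replicate 1 peaks were placed at random on their own chromosomes, 75.5 ± 8.43 (SD over 1000 placements) overlapped a replicate 2 peak, so that the observed number was 30.4 times higher (one-sided permutation by placement, p = 0.000999, the smallest possible). Against peaks moved by only 20 to 500 kb, a comparison chosen after the data were seen, the number was 13.4 times higher. Neither comparison takes account of where reads can be mapped or where chromatin is open. No IgG peak list was compared, so the excess does not show that the shared sites are specific to AHCY. On chromosomes 6 and 8 alone the excess was lower, at 10.8 times random placement and 4.61 times the moved peaks, and without these chromosomes it was 50.1 and 22.5 times. Randomly placed peaks overlapped more often on chromosomes 6 and 8 (7.95%, against 0.945% elsewhere), which limits how high the excess can rise there. The lower excess is therefore not a sign of weaker agreement. Overlapping peaks were also well centred on each other: across 2330 overlapping pairs the midpoints lay a median of 189 bp apart (interquartile range 68.1 to 422.6 bp), and a median of 1358.5 bp was common to both peaks.

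Shared peaks had higher scores than unshared ones in both replicates. The median score in replicate 1 was 75.5 for shared and 61.3 for unshared peaks, a difference of 14.2 (two-sided permutation test, p = 1e-05, the smallest possible). In replicate 2 the medians were 99.1 and 69.1, a difference of 30.0 (two-sided permutation test, p = 1e-05, again the smallest possible). Shared peaks were also wider, by 223 bp in replicate 1 and 152.5 bp in replicate 2 at the median. When replicate 1 peaks were divided by score into 4 groups of equal size, 32.2% were shared in the weakest group, 43.3% and 56.2% in the middle groups and 74.0% in the strongest. On chromosomes 6 and 8 the same groups reached 71.5, 81.9, 91.5 and 100%, the last being 120 of 120 peaks, and on the other chromosomes 27.4, 37.8, 52.9 and 70.9%.

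**Figure D3:**
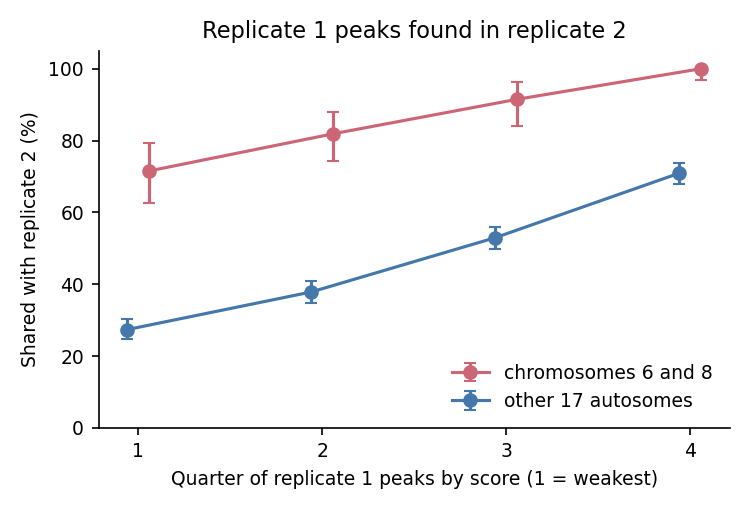
Share of replicate 1 AHCY peaks that overlap a replicate 2 peak (percent, with exact 95% intervals), in 4 groups of replicate 1 score from the weakest to the strongest, on chromosomes 6 and 8 (red) and on the other 17 autosomes (blue). The share rises from 71.5 to 100% on chromosomes 6 and 8 and from 27.4 to 70.9% on the others.

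Among shared peaks, the scores of the replicates rose together, but weakly. Across 2296 pairs of peaks, Spearman's rho was 0.235 and Pearson's r of the log scores 0.274 (two-sided permutation tests, p = 1e-05 each, the smallest possible), and r was 0.271 without the 2 peaks farthest from the median. Apart from chromosomes 6 and 8 the relation was closer, with rho 0.287 and r 0.348 over 1889 pairs. On chromosomes 6 and 8 alone, rho was 0.302 and r 0.342 over 407 pairs. Both lists start at a score of 50, so sites that scored lower in either are missing, which can lower rho and r. These relations run across peaks of 1 pair of libraries, and peaks are not independent replicates. Whether the score measures enrichment or significance, which depends on read depth, is not given in the sources used here.

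**Figure D4:**
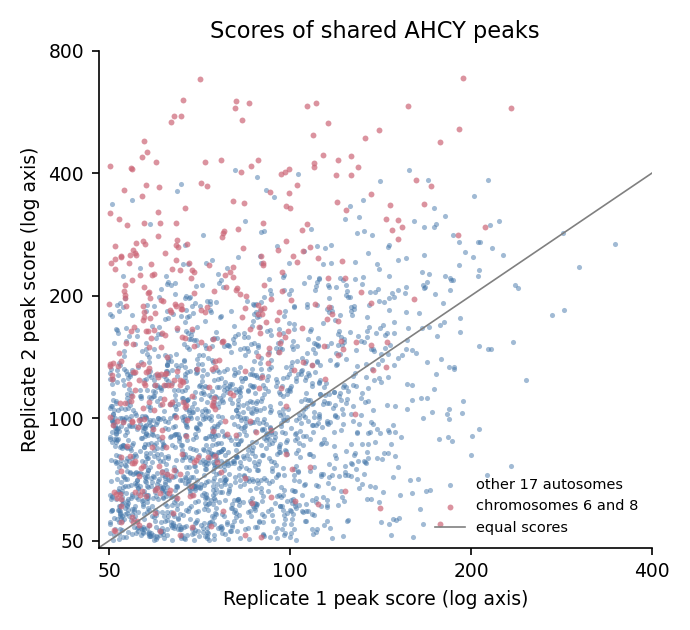
Score of each shared AHCY peak in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, on chromosomes 6 and 8 (red) and on the other 17 autosomes (blue); the line marks equal scores. Across the 2296 pairs rho was 0.235, and the pairs of chromosomes 6 and 8 lie higher on the replicate 2 axis.

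Strong sites found in both replicates can be named by position (mm9, positions counted from 1). The best were chosen by the mean of their 2 ranks, taken in lists of unequal length. Merging overlapping peaks of the replicates gave 2278 shared regions, with a median width of 2011.5 bp and a total of 5.24 Mb. The region with the best mean rank lay on chromosome 8 at 87183384 to 87189898, with a score of 232.98 (rank 14) in replicate 1 and 578.53 (rank 12) in replicate 2. The next was on chromosome 6 at 86474583 to 86477720, with scores of 194.1 and 685.1. Chromosome 8 at 112301961 to 112303821 (190.8 and 514.1) and chromosome 6 at 120614462 to 120617619 (177.5 and 477.1) came after these. Of the best 10 regions, the remaining 6 lay on chromosome 9 at 114468909 to 114474339, chromosome 3 at 58808812 to 58811653, chromosome 6 at 119428566 to 119431703, chromosome 11 at 97519771 to 97524512, chromosome 8 at 13103499 to 13106748 and chromosome 9 at 44688314 to 44691743. The widest region measured 13300 bp, on chromosome 11 at 97529172 to 97542471, next to a region of the best 10. The other 4 of the 5 widest were on chromosome 6 at 30116563 to 30128712 and on chromosome 8 at 123091923 to 123102965, 73285630 to 73296362 and 72403237 to 72413415. These 5 wide regions ranked 1374 to 3663 among the 4465 peaks of replicate 1, and 11 to 451 among the 11733 of replicate 2. Their replicate 1 scores ran from 54.5 to 81.0, on both sides of the list median of 67.1. They lie on chromosomes 6 and 8 or between 96 and 98 Mb of chromosome 11, where replicate 2 had its surplus. Gene names cannot be given for these regions, because no annotation of their build was at hand.

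Chromosomes 6 and 8 weighed on these ranks through replicate 2. Of the best 100 peaks by score, 82 lay on chromosomes 6 and 8 in replicate 2 and 9 in replicate 1. In replicate 1, 88 of the best 100 were shared, and in replicate 2, 64. Among strong sites outside these chromosomes, a choice made after the data were seen, were chromosome 17 at 34254943 to 34260062 (222.9 in replicate 1 and 304.8 in replicate 2), chromosome 4 at 46356473 to 46359315 (214.8 and 298.5) and chromosome 4 at 133368702 to 133371203 (284.5 and 285.5). With each rank divided by the length of its list, their mean ranks were 0.0087, 0.0095 and 0.0090. Some of the best 10 regions ranked lower by this measure, such as chromosome 11 at 97519771 (0.0124) and chromosome 9 at 44688314 (0.0155). Membership of the best 10 therefore depends on how the ranks of the 2 lists are combined. Some strong peaks had no partner. The best of these in replicate 1 were on chromosome 19 at 59418622 to 59421208, with a score of 262.8 (rank 6), and on chromosome 5 at 149862097 to 149865976, with 260.2 (rank 7). In replicate 2 they were on chromosome X at 166420848 to 166426070, with 1307 (rank 1), and on chromosome 8 at 86422355 to 86426603, with 656.4 (rank 4).

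Shared regions were unevenly spread over the chromosomes. Relative to the span of each chromosome, they were densest on chromosome 11, with 210 regions against 106.9 expected (1.96 times), and chromosome 8, with 214 against 116.4 (1.84 times). Chromosomes 19 (1.62 times), 6 (1.43 times) and 17 (1.27 times) were also denser. Chromosome 14 held 43 against 104.6 expected (0.411 times), and chromosomes 16 (0.698 times), 1 (0.748 times) and 3 (0.767 times) were sparser too. Chromosome X held 0 against 115.0 expected, an outcome fixed by replicate 1, which listed 0 peaks there. Its span was counted in this and the following density tests, which lowers the number expected on every other chromosome. The tests were not run without it, so results near the threshold may depend on it. With chromosome X counted, 10 of 20 chromosomes passed an adjusted threshold of 0.05 by exact binomial tests with Benjamini-Hochberg adjustment. Without chromosomes 6 and 8, chromosomes 3 and 16 no longer passed (adjusted exact binomial p = 0.0803 and 0.0503), while chromosomes 2 and 9 newly passed as denser (1.25 and 1.29 times). With the better-scoring 50% of each list, chromosomes 1 and 3 no longer passed (adjusted exact binomial p = 0.165 and 0.0661), while chromosome 12 newly passed as sparser (0.681 times). For chromosomes 6 and 8, 1 library decided the result. With replicate 1 peaks alone, chromosome 6 stood at 0.881 times (adjusted exact binomial p = 0.0673) and chromosome 8 at 1.08 times (adjusted exact binomial p = 0.218). With replicate 2 peaks alone, these stood at 3.999 and 5.957 times, which raises the number expected on every other chromosome. The other chromosomes were therefore compared with each replicate alone on the chromosomes other than 6 and 8, a choice made after the data were seen. Chromosome 14 then stood at 0.467 times in replicate 1 and 1.35 times in replicate 2. With its stretch from 47 to 63 Mb and that of chromosome 11 left out it was sparser in both, at 0.541 and 0.738 times. The stretch on chromosome 14 was chosen for its replicate 2 surplus, so leaving it out was bound to lower the replicate 2 ratio. With both stretches counted, chromosomes 11 (1.86 times in replicate 1 and 2.35 in replicate 2, or 1.78 and 1.89 without them), 17 (1.505 and 1.246) and 19 (1.71 and 1.53) were denser in both replicates. Chromosomes 1 (0.804 and 0.707), 3 (0.725 and 0.708) and 16 (0.775 and 0.668) were sparser in both. Of the chromosomes that had not passed with shared regions, chromosome 2 was denser (1.21 and 1.15) and chromosome 12 sparser (0.788 and 0.814) in both replicates by the same tests.

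On the chromosomes singled out as denser or sparser, the best-ranked regions outside those already named were as follows. Chromosome 11 had a region at 61667310 to 61669732 (145.9 in replicate 1 and 267.1 in replicate 2). Chromosome 19 had regions at 56795393 to 56798710 (173.8 and 294.9) and 3766568 to 3768916 (190.9 and 271.4), and chromosome 17 had one at 87844968 to 87847154 (167.2 and 251.5). On chromosome 14 the best were at 22803763 to 22807827 (190.9 and 238.2) and 79880225 to 79882121 (145.7 and 263.8). Chromosome 1 had 154748455 to 154751377 and 10221779 to 10223724, chromosome 3 had 58218468 to 58221124, and chromosome 16 had 98072159 to 98074153 and 8829024 to 8831988.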

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

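The settings on or without chromosomes 6 and 8, those without the stretches of 11 and 14, and the placement by moving peaks were chosen after the data were seen; the others were fixed beforehand. The number of shared peaks was 1113 with the better-scoring 50% of each list and 1454 with lists of equal length; each replicate alone gives its own list, 4465 to 11733 peaks. The share of replicate 1 peaks that was shared became 44.9% with reciprocal overlap, 49.9% with the better-scoring 50%, 32.6% with equal length and 47.3% without chromosomes 6 and 8. The share of replicate 2 peaks became 17.1% with reciprocal overlap, 32.5% with equal length and 34.9% without chromosomes 6 and 8. Peak numbers were 2232 and 5864 in the better-scoring 50% of the lists, and replicate 2 had 5442 peaks without chromosomes 6 and 8. With each replicate alone, 12 to 20 chromosomes passed the density test, and the ratio of observed to expected regions turned on chromosomes 6 (0.881 to 3.999), 17 (0.649 to 1.51) and 19 (0.798 to 1.72). The turns on 17 and 19 come from the replicate 2 peaks on chromosomes 6 and 8, which raise every other expected number: with replicate 2 alone on the other chromosomes the ratios were 1.25 and 1.53, while chromosome 14 turned to 1.35. That turn comes from its stretch from 47 to 63 Mb, without which (and that of chromosome 11) the ratio was 0.738; for chromosome 6 the cause was not tested. The excess over random placement, the higher scores of shared peaks and the relation of scores kept their direction and their side of the threshold under every alternative run for them, with an excess of 13.4-fold (moved peaks) to 51.4-fold (better-scoring 50%); on chromosomes 6 and 8 alone it was 10.8-fold, and 4.61-fold over moved peaks. In all, 107 values under an alternative held (a tested value kept its direction and side, a share stayed within its 95% interval, a count within 1.5 times), 15 moved beyond that, 7 fell short of the threshold and 4 turned. Some of those that held could not change. Replicate 1 had 0 peaks on chromosome X, so autosomes only left its list and the shared peaks as they were. For the same reason the density of shared regions on chromosome X was fixed at 0. The tally is therefore not a measure of robustness. Alternatives fixed beforehand for peaks near start sites and for gene lists (other windows, the better-scoring 50%, each replicate alone) were not run, since those tests could not be made. No paired analysis was possible because the replicate numbers are shared with groups that are not analysed here, and the peak lists come from 1 group. Read depth is unknown, so how far it limits either list cannot be given.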

Other observations

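All tests in this part were chosen after the results they bear on had been seen.

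Replicate 2 peaks without a partner were not scattered evenly. In windows of 5 Mb, their number followed the number of replicate 1 peaks, with Spearman's rho of 0.913 over 30 windows of chromosome 6 and 0.883 over 27 windows of chromosome 8. Pearson's r was 0.871 on chromosome 6 (0.839 without the 2 windows farthest from the median) and 0.769 on chromosome 8 (0.807). For both chromosomes the adjusted permutation p of rho was 2.11e-05, over 19 chromosomes tested. On the other 17 autosomes rho had a median of 0.794 and ranged from 0.365 on chromosome 14 (adjusted permutation p = 0.0805, r -0.109) to 0.871 on chromosome 4. These relations run across windows within 1 pair of libraries, and windows are not independent replicates. Gene density and mappable sequence, which may shape the peaks of any library, were not taken into account. Windows of the other autosomes mostly held fewer replicate 2 peaks without a partner, and counting error can lower rho there.

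The pattern that most calls for a follow-up is the surplus of replicate 2 peaks on chromosomes 6 and 8. A replicate 2 library equally more sensitive everywhere is argued against as the only cause by the other 17 autosomes. The highest ratio there was 3.94, on chromosome 14, below the lower limit of 10.4 on chromosome 6. Chromosomes 6 and 8 were singled out by these same counts. Replicate 2 also listed more peaks elsewhere, with ratios of 1.13 to 1.46 on the 15 autosomes other than 6, 8, 11 and 14. A general difference in sensitivity beside another cause therefore stays open. A few local clusters are argued against by the 5 Mb windows of chromosomes 6 and 8, 98.2% of which lay above the 95th percentile of the others. More copies of chromosomes 6 and 8 in the replicate 2 cells than in its control, or a control that lacked reads there, may each account for the surplus. Shared peaks there had replicate 2 scores higher relative to replicate 1, by 0.88 on the log2 scale compared with the other autosomes, but peak numbers and scores come from the same list, so this favours neither, and the 2 cannot be told apart without control reads. A biological change of AHCY binding on these chromosomes was not tested, since both libraries belong to 1 group.

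A second pattern is the stretch of chromosome 14 from 45938846 to 63740632, the longest gap between replicate 1 peaks (17.8 Mb). Replicate 2 listed 224 peaks inside it, while the next 9 gaps, of 9.75 to 12.5 Mb, held 0 to 4. The stretch had already stood out for its many replicate 2 peaks, which may themselves come from a copy number or control difference. Whether it holds few sites is therefore not decided by them. The density of replicate 1 on the rest of the chromosome would give 17.5 peaks there. A copy number or control difference between the replicates may account for the gap, but this cannot be told apart from a change in AHCY binding there, because the lists hold no control signal.

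A last pattern is that outside chromosomes 6 and 8 a partner was found for 47.3% of replicate 1 peaks, so that most had none. A candidate explanation is that many are sites under the calling limit of replicate 2. On chromosomes 6 and 8, where replicate 2 lists many more peaks, 71.5% of the weakest of the 4 score groups of replicate 1 peaks had a partner (exact 95% interval 62.7 to 79.3%), against 15.7% after moving these peaks by 20 to 500 kb, and on the other chromosomes 27.4% did, against 1.97%. In the strongest score group the share on the other chromosomes was 70.9%, so some of the strongest replicate 1 peaks also lacked a partner. How far the calling limit accounts for these was not tested. No biological explanation was tested for this pattern. Read depth per chromosome in the AHCY and control libraries would test these hypotheses.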
